A study of Caenorhabditis elegans with 30 samples.

How the data were processed

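Counts of reads per gene for 30 libraries were taken as deposited. Per the submitters' processing notes, base calls were converted with bcl2fastq 1.8.4, reads were aligned to the genome build WBcel235 with STAR 2.4.1d, and counts per gene were made with featureCounts 1.4.6-p4. Per the labels, libraries were made with a TruSeq RNA v2 kit, which selects polyadenylated RNA and does not mark strand. The count table held 46748 genes, of which 43693 had a gene symbol in the reference annotation of the same build. The 12 protein-coding genes of the mitochondrial genome were named by their coordinates. Every column of the table was matched to a library, leaving 0 unmatched. Library totals ran from 31835911 to 44987307 counts, ribosomal RNA genes took 0.025% to 3.58% of the counts and mitochondrial genes 0.625% to 1.11%.

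A table of RPKM was also deposited by the authors, and it was not used for any comparison. Its divisors do not follow the columns, because the 30 totals had been applied down the genes and not across the libraries. This was checked on 4480 genes with an RPKM above 20 in every library. Totals applied down the genes gave 1 length per gene, within 0.1%, for 100% of these values. The total of the own library did so for 1.14%. Under this pattern 3.33% of all values in the table carry the total of their own library. The wrong total was between 0.708 and 1.41 times the right one.

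The comparisons, the gene lists, the rule for naming genes, the thresholds and most of the alternative settings were chosen before the data were examined. Genes with low counts were removed with filterByExpr, libraries were scaled by the trimmed mean of M values, and robust quasi-likelihood models were fitted with edgeR 4.0.16 in R 4.3.3. The 15 libraries of a prefix were fitted together with 5 group means, and each RNAi group was compared with the L4440 group of that prefix. This left 16495 genes in the ZK fit and 15795 in the RM fit, each with 10 residual degrees of freedom, and scaling factors of 0.923 to 1.13 and 0.962 to 1.11. L4440_RM was compared with L4440_ZK, and pairs of RNAi effects with each other, in a fit of all 30 libraries with 16867 genes. p-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the quasi-likelihood F. A fold against a group with 0 counts was given as a lower bound with a floor of 3 counts over the group, which covers counting error only.

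On simulated counts with the spread of the ZK libraries, 87% of genes changed 1.5-fold and 97% of genes changed 2-fold were recovered, with 8 false calls among 14479 genes. With the spread of the RM libraries these were 60% and 90%, with 7 false calls among 15445 genes. In both cases 0 genes were called between simulated groups without a change.

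Gene lists were drawn up by gene name or from general knowledge of gene function, 46 in all, and those with at least 5 tested members were tested with camera in limma 3.58.1, with its preset correlation of 0.01 between members. The adjustment ran over the lists of the 8 RNAi comparisons together and over those of the L4440 comparison apart. Each list was tested again with a correlation estimated from the data and with fry.

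Genes were named by rule. Each target was named in its own treatment. Among genes past the threshold, with all 3 RNAi libraries on the same side of all 3 controls and a mean over the 6 libraries of at least 1 CPM, the 8 largest rises and 8 largest falls were eligible, and next the 4 smallest p-values among the rest. From each list that passed, or that had at least 3 members past the threshold, up to 4 members with the smallest p were eligible. For the L4440 groups the 5 largest differences on each side were taken. Neighbours of the targets, and the genes that rose in at least 6 of the 8 treatments, were added after the values had been seen. The text names a part of the eligible genes.

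The settings chosen in advance were relative log expression factors, no filter on low counts, DESeq2 1.42.0 and a fit of the 6 libraries compared. They also included a fit of all 30 libraries, all 6 L4440 libraries as 1 control group and leaving out each library in turn. The others were a covariate for the punctuation in the sample descriptions and a block for the replicate number. Titles carry 1 running number per library, and the replicate number is its order within a group. Scaling by library totals, a fit without the C01A2.5 libraries, and a fit without L4440_RM replicate 3 and F26D12.1 replicate 3, and a fit of replicates 1 and 2 alone in every RM group were added after the data had been examined. Correlations between comparisons used genes with a control level of at least 1 CPM, and the share due to common controls was taken from 20 simulations per prefix. Independent lists would share n1 × n2 / N genes, with N the genes tested in both fits.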

Results

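Polyadenylated RNA was sequenced from whole hermaphrodites of the Caenorhabditis elegans wild-type strain N2, aged 5 days, that had been fed bacteria making double-stranded RNA against a chosen gene. The 30 libraries fall into 8 RNAi treatments of 3 libraries each and 6 libraries from animals fed L4440, the empty feeding vector. Library titles carry the prefix ZK or RM, and each prefix holds 15 libraries in 5 groups of 3. The 4 treatments of a prefix were compared with the 3 L4440 libraries of the same prefix, called L4440_ZK and L4440_RM. The labels give no purpose beyond the treatments, so each comparison asks which transcripts differ from the empty vector when the named gene is the target. Library totals ran from 31835911 to 44987307 gene counts, and 28701 of the 46748 genes in the table had at least 1 count. The biological coefficient of variation between replicates was 5.4% in the ZK libraries and 11.7% in the RM libraries.

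Gene values are log2 fold changes against the matching L4440 group ± standard error, with n = 3 libraries per group, and levels are counts scaled to library size (CPM), mean ± SD. A gene is said to have risen or fallen where edgeR's quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05 across all genes tested. For each of the genes named for a large rise or fall, all 3 treated libraries lay on the same side of all 3 control libraries. The p-values of single genes measure the spread between libraries. Nothing in the labels says whether the 3 libraries of a group came from separate cultures. The camera p-values of gene lists instead set the members of a list against the other genes tested. With the preset correlation, camera treats the members of a list as nearly independent. Values with a correlation estimated from the data do not rest on that setting. The library kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart, and near-identical paralogs such as the histone, major sperm protein and yolk protein genes share reads.

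R186.7 is pnn-1, named after the splicing-associated protein pinin, a protein-coding gene (WBGene00011308) at chromosome V 12971110 to 12973281 of WBcel235. Its transcript fell to 19.6 ± 3.81 CPM from 117.5 ± 4.38 in L4440_ZK, a log2 fold change of -2.58 ± 0.10 (adjusted p = 3.71e-11). The RNAi libraries held 17.4, 17.4 and 24.0 CPM and the controls 122.6, 114.7 and 115.3. The end of pnn-1 overlaps shw-3 on the other strand, which had -0.26 ± 0.24 (adjusted p = 0.658). Of 29 histone genes 11 rose after pnn-1 RNAi (adjusted p = 0.00344 for the list with an estimated correlation), and the arginine kinase gene argk-1 went from 13.3 ± 2.00 to 55 ± 1.83 CPM (2.06 ± 0.08).

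Of 16495 genes tested, 421 changed after R186.7 RNAi, 307 upward and 114 downward. Besides argk-1, the largest rises included F48E3.2 (2.25 ± 0.10), the C-type lectin gene clec-258 (2.22 ± 0.14), B0238.15 (2.22 ± 0.21), H20E11.2 (2.11 ± 0.17), the chemoreceptor family gene str-7 (1.95 ± 0.09) and the cytochrome gene cyp-35B1 (1.49 ± 0.10). The cystathionine gamma-lyase gene cth-1 rose by 1.14 ± 0.05, among the smallest p-values. Apart from the target pnn-1 (-2.58 ± 0.10), falls were smaller. The gene tiam-1, which encodes a Rac exchange factor, had -1.33 ± 0.12 and C16C8.20 -1.32 ± 0.15. Values were -0.89 ± 0.09 for E_BE45912.2, -0.89 ± 0.07 for Y38C1AA.12, -0.84 ± 0.10 for C26D10.3 and -0.70 ± 0.08 for the lipoyltransferase gene lipt-1. More than 2-fold changes numbered 45 upward and 7 downward. Relative log expression factors called 444 genes, 224 higher and 220 lower, library totals 588, 511 higher and 77 lower, and DESeq2 648, 226 higher and 422 lower, so the balance of rises and falls depends on the scaling. The count fell to 266 or 254 without R186.7 replicate 1 or 2 and to 268 or 245 without L4440_ZK replicate 2 or 3, and a fit of all 30 libraries gave 161.

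Of 29 histone genes tested, 11 rose and 0 fell (16 rose when adjusted over the list alone), with a median of 0.69 (camera adjusted p = 3.54e-24, and adjusted p = 0.00344 with an estimated correlation). Examples are his-63 (1.4 ± 0.17), his-59 (1.14 ± 0.10), his-67 (1.12 ± 0.11) and his-61 (0.87 ± 0.10). The list holds 72 histone genes, and 29 passed the filter on low counts. Because polyadenylated RNA was selected, these counts do not measure histone transcripts without a poly(A) tail. Among 128 C-type lectin genes, 6 rose and 0 fell (8 rose adjusted over the list alone). clec-218 (0.95 ± 0.09) and clec-66 (0.50 ± 0.10) were among them, with a camera adjusted p of 0.0191 for the list, and adjusted p = 0.534 with an estimated correlation. In the small RNA pathway 3 of 43 genes fell and 0 rose (4 fell adjusted over the list alone). These were the RNAi nuclease gene rde-8 (-0.31 ± 0.05), nrde-1 (-0.25 ± 0.05) and the microRNA Argonaute gene alg-1 (-0.24 ± 0.06), with a camera adjusted p of 1.18e-04 and adjusted p = 0.546 with an estimated correlation. The mitochondrial unfolded protein response list had 3 falls among 15 genes (4 adjusted over the list alone), in the chaperonin gene hsp-60 (-0.27 ± 0.07), hmg-5 (-0.25 ± 0.05), which packages mitochondrial DNA, and the protease gene lonp-1 (-0.22 ± 0.05). Its camera adjusted p was 0.00157, and adjusted p = 0.318 with an estimated correlation.

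**Figure D1:**
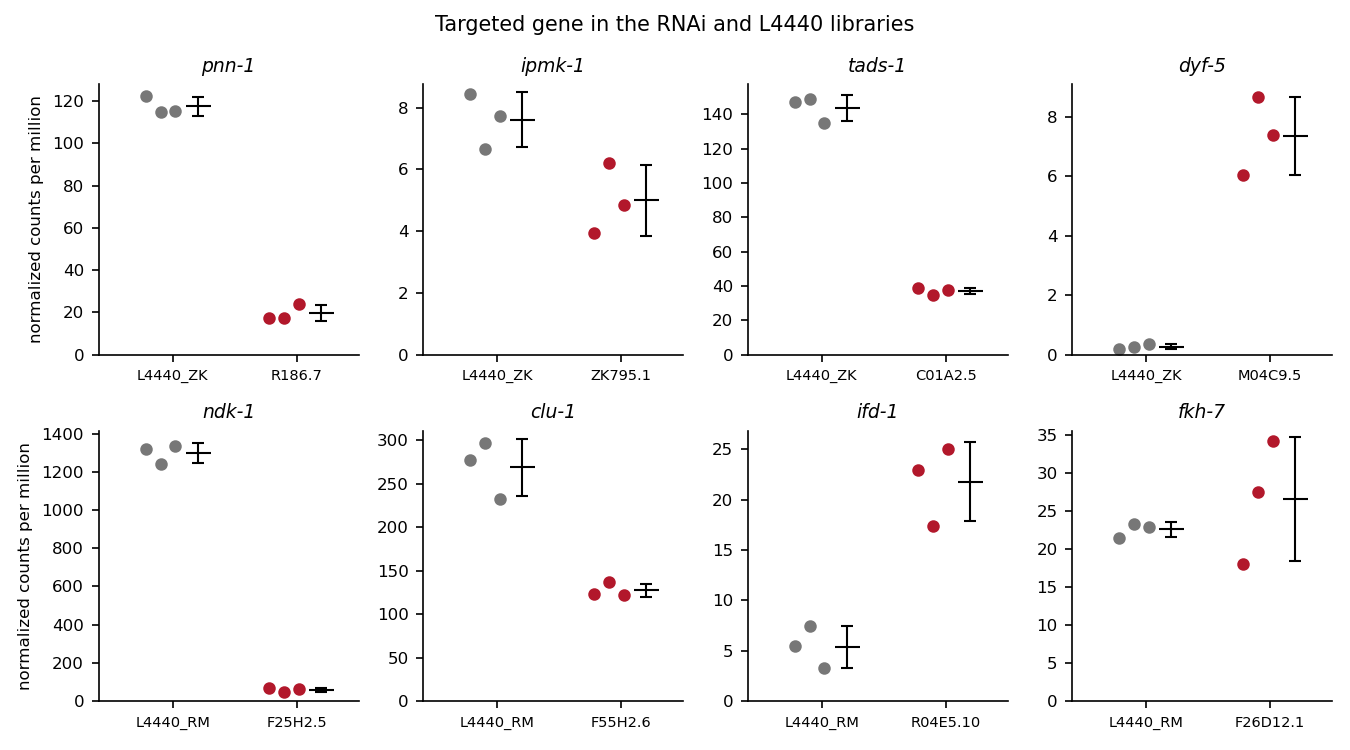
Level in CPM of each targeted gene in the 3 libraries of its own RNAi treatment and the 3 L4440 libraries of the same prefix, 1 panel per gene with its own vertical axis from 0; points are libraries and bars mean ± SD. pnn-1, ipmk-1, tads-1, ndk-1 and clu-1 were lower than in L4440, dyf-5 (7.36 against 0.27) and ifd-1 (21.8 against 5.40) were higher, and the fkh-7 libraries overlapped.

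ZK795.1 is ipmk-1, an inositol polyphosphate multikinase gene (WBGene00014081, protein coding) at chromosome IV 12548124 to 12554681 of WBcel235. The transcript was low in the controls and fell to 5.00 ± 1.15 CPM from 7.62 ± 0.90, a log2 fold change of -0.62 ± 0.12 (adjusted p = 0.00115). The RNAi libraries held 3.93, 6.22 and 4.84 CPM and the L4440_ZK libraries 8.46, 6.66 and 7.73. Rises were found in 6 of 43 fatty acid oxidation genes, 17 of 110 collagen genes and 5 of 38 muscle genes (adjusted p = 0.0448, 0.583 and 0.534 for the lists with an estimated correlation). The lysozyme genes lys-10 (-1.86 ± 0.12) and lys-7 (-0.73 ± 0.06) and the insulin-like gene ins-7 (-0.93 ± 0.09) fell.

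In all, 328 of 16495 genes changed after ZK795.1 RNAi, 216 upward and 112 downward, and 26 of the rises and 10 of the falls exceeded 2-fold. clec-258 (2.1 ± 0.14), H20E11.2 (1.97 ± 0.17), argk-1 (1.90 ± 0.08), F48E3.2 (1.89 ± 0.10), cyp-35B1 (1.72 ± 0.10), fipr-1 (1.6 ± 0.19), irg-6 (1.5 ± 0.12) and vmo-1 (1.46 ± 0.22) showed the largest rises. The largest falls included idpc-2 (-2.25 ± 0.31), lys-10, Y105C5A.13 (-1.72 ± 0.18), the C-type lectin gene clec-5 (-1.28 ± 0.11), B0024.4 (-1.27 ± 0.10), the carnitine palmitoyltransferase gene cpt-4 (-1.04 ± 0.13) and the exchanger gene ncx-9 (-1.01 ± 0.16). The peptide transporter gene pept-1 (-0.61 ± 0.07) and the protease gene cpr-5 (-0.71 ± 0.06) also fell. Relative log expression factors gave 173 higher and 190 lower genes, library totals 165 and 155, and DESeq2 204 and 389 of 593 genes. Leaving out ZK795.1 replicate 3 raised the count to 1304 genes, 425 higher and 879 lower, and leaving out ZK795.1 replicate 1 or L4440_ZK replicate 2 lowered it to 190 or 209. A fit of all 30 libraries gave 44 genes.

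Fatty acid oxidation genes rose as a group: 6 of 43 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.12 (camera adjusted p = 1.20e-06, and adjusted p = 0.0448 with an estimated correlation). They include cpt-3 (0.57 ± 0.09), hacd-1 (0.39 ± 0.07) and acox-1.4 (0.39 ± 0.08), while cpt-4 is the fall. Of 110 collagen genes, 17 rose and 0 fell (24 adjusted over the list alone). col-119 (0.56 ± 0.07) and col-122 (0.39 ± 0.05) are members, and the camera adjusted p was 1.83e-07, and adjusted p = 0.583 with an estimated correlation. In muscle, 5 of 38 genes rose and 0 fell (18 adjusted over the list alone), including tnt-2 (0.31 ± 0.06) and act-4 (0.24 ± 0.05), which turn negative (-0.12 each) with all 6 L4440 libraries as control. For muscle the camera adjusted p was 3.40e-10, and adjusted p = 0.534 with an estimated correlation. Among 27 genes known to be raised by the insulin-pathway factor DAF-16, 8 rose and 1, lys-7, fell (12 and 2 adjusted over the list alone). The ferritin gene ftn-1 (0.64 ± 0.09), pck-1 (0.36 ± 0.05) and icl-1 (0.34 ± 0.05) were among the rises, and the camera adjusted p of 4.03e-05 became adjusted p = 0.534 with an estimated correlation. The desaturase gene fat-7 (0.56 ± 0.06), the lipase gene lipl-1 (0.83 ± 0.07) and the glycolytic genes gpd-2 (0.33 ± 0.06) and gpd-3 (0.30 ± 0.05) rose too. The 30 major sperm protein genes had a median of 1.54, but 1 of them rose (1 adjusted over the list alone), msp-51 (2.11 ± 0.53). Their camera adjusted p was 6.64e-07, and adjusted p = 0.694 with an estimated correlation. Their mean log2 level was -0.98 and -1.0 in ZK795.1 replicates 1 and 2 but -2.60 in replicate 3, within the -2.19, -2.15 and -3.21 of L4440_ZK, and 13 of the genes rose without replicate 3. On the third principal component of the ZK libraries replicate 3 also lay near the L4440_ZK libraries, at 2.1 against 3.5, 2.2 and 1.8, with the other ZK795.1 libraries at -17.1 and -26.

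C01A2.5 is tads-1, a protein-coding gene (WBGene00007217) at chromosome I 13384752 to 13387084 of WBcel235, whose transcript fell to 37.02 ± 1.94 from 143.8 ± 7.84 CPM (-1.96 ± 0.07, adjusted p = 4.33e-18). The RNAi libraries held 38.7, 34.9 and 37.5 CPM and the controls 147.3, 149.3 and 134.9. The neighbouring gene oxa-1, 735 bp away, also fell (-1.09 ± 0.06), while C01A2.6 at 381 bp had -0.45 ± 0.28 (adjusted p = 0.125). The transcriptome changed almost throughout. Sperm transcripts that were near absent from L4440_ZK became abundant. Major sperm protein genes took 0.354% of all counts against 0.001%, and the sperm gene smz-1 went from 126 counts over the 3 controls to 28566 over the 3 RNAi libraries (7.74 ± 0.10). Of 32 oocyte, eggshell and early embryo genes 29 fell, for example egg-2 (-1.73 ± 0.06), with adjusted p = 0.534 for the list with an estimated correlation. Of 16495 genes, 14524 changed, 8528 upward and 5996 downward, and 5302 rises and 1586 falls exceeded 2-fold. The number of genes with counts rose to 22545 per library from 19168.

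The median log2 fold change of all genes after C01A2.5 RNAi was 0.42, and it moved by -0.23 with relative log expression factors and by 0.24 with library totals, so a list is read against that level. All 30 major sperm protein genes rose, with a median of 9.23, 8.81 above the median of all genes (camera adjusted p = 2.89e-17, and adjusted p = 0.534 with an estimated correlation). Their control libraries were often at 0, and the median was 9.22 with such genes set to their lower bound. All 28 other sperm genes rose as well, with a median of 8.00 (camera adjusted p = 1.51e-35, and adjusted p = 0.0498 with an estimated correlation). The phosphatase gene gsp-4 (9.5 ± 0.14), ssp-10 (6.62 ± 0.09) and spe-15 (4.37 ± 0.07) are examples, and outside the list spch-3 (9.13 ± 0.13) and smz-2 (8.36 ± 0.11) rose with smz-1. Some genes had 0 counts in all 3 controls and were placed on a floor of 3 counts over the group. C04F12.12 was at least 805.2-fold higher, Y41C4A.18 at least 582.8-fold higher, F38H4.6 at least 532.1-fold higher and F56D6.19 at least 437.2-fold higher. The C-type lectin gene clec-79 (8.53 ± 0.12) and the insulin-like gene ins-37 (8.54 ± 0.16) rose from near absence. Of all C-type lectins, 92 of 128 genes rose and 11 fell (90 and 11 adjusted over the list alone; camera adjusted p = 0.0304, and adjusted p = 0.534 with an estimated correlation).

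Of 32 oocyte, eggshell and early embryo genes, 29 fell and 3 rose after C01A2.5 RNAi, with a median of -1.36 (camera adjusted p = 5.22e-12, and adjusted p = 0.534 with an estimated correlation). They include cpg-3 (-1.63 ± 0.05), gna-2 (-1.5 ± 0.05) and egg-5 (-1.5 ± 0.05). Among 42 genes of germline proliferation and meiosis, 40 fell and 0 rose (camera adjusted p = 5.78e-09, and adjusted p = 0.534 with an estimated correlation), such as the synaptonemal complex gene syp-2 (-1.38 ± 0.06), zim-1 (-1.17 ± 0.05) and htp-3 (-1.11 ± 0.05). All 65 mitochondrial ribosomal protein genes fell, mrpl-11 by -1.12 ± 0.05 (camera adjusted p = 2.04e-09, and adjusted p = 0.534 with an estimated correlation). So did 32 of 33 proteasome genes, among them pas-7 (-1.04 ± 0.05), while rpn-6.2 rose (1.66 ± 0.06; camera adjusted p = 5.48e-06, and adjusted p = 0.534 with an estimated correlation). In the small RNA pathway 33 of 43 genes fell and 6 rose, with rde-8 (-1.28 ± 0.05) and rde-4 (-1.25 ± 0.05) among the falls (camera adjusted p = 1.55e-04, and adjusted p = 0.546 with an estimated correlation). The same members passed in each of these 5 lists when adjusted over the list alone.

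Yolk protein genes did not fall with the oocyte genes: 5 of 6 rose (camera adjusted p = 0.775), including vit-2 (0.81 ± 0.10) and vit-6 (0.56 ± 0.11). Yolk transcripts made up 7.01 ± 1.31% of counts against 3.95 ± 0.14%. The lists of ciliated neurons, neuropeptides and muscle lay above the median of all genes without passing the list test, and the cuticle collagens named by phenotype lay below it (-0.04, camera adjusted p = 0.823). In ciliated neurons 42 of 48 genes rose and 3 fell (median 1.41, camera adjusted p = 0.249), for example ocr-2 (3.35 ± 0.20) and dyf-7 (2.42 ± 0.16). Among 128 neuropeptide genes 108 rose and 4 fell (camera adjusted p = 0.0569), with nlp-4 at 5.58 ± 0.17 and ins-7 at 2.48 ± 0.08. Of 38 muscle genes 34 rose and 2 fell (camera adjusted p = 0.0503), such as atn-1 (1.46 ± 0.06) and act-4 (0.99 ± 0.05). Adjusted over the list alone, the counts of the yolk, sperm, neuron, neuropeptide and muscle lists were unchanged. The cuticle gene dpy-17 rose (2.54 ± 0.10), while col-73 (-5.22 ± 1.14), col-139 (-4.73 ± 0.76), scl-20 (-4.73 ± 0.26) and the dehydrogenase gene dhs-26 (-4.1 ± 0.14) were among the deepest falls.

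M04C9.5 is dyf-5, a gene for a MAP-kinase-like kinase of ciliated sensory neurons (WBGene00001121, protein coding), at chromosome I 9359067 to 9364238 of WBcel235. In the libraries labelled M04C9.5 its transcript was not lowered but higher, at 7.36 ± 1.31 against 0.27 ± 0.09 CPM, a log2 fold change of 4.75 ± 0.21 (adjusted p = 8.03e-17). The treated libraries held 231, 371 and 295 counts of dyf-5 and the controls 7, 9 and 15. The counts do not show whether these animals took up double-stranded RNA against dyf-5 or carry the right label, so values of these libraries are tied to the label alone. The overlapping gene ppfr-1 on the other strand had 0.12 ± 0.06 (adjusted p = 0.163). In the libraries labelled M04C9.5 all 6 yolk protein genes and 14 of 19 epidermal antimicrobial peptide genes fell (adjusted p = 0.115 and 0.0448 for the lists with an estimated correlation). The gene fmo-2, a flavin monooxygenase gene, rose by 3.32 ± 0.12, from 2.49 ± 0.52 to 24.7 ± 2.94 CPM.

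Among 16495 genes, 3259 changed in the libraries labelled M04C9.5, 1692 upward and 1567 downward, with 513 rises and 120 falls over 2-fold. Other large rises were in F20G2.1 (3.09 ± 0.13), the acyltransferase family gene oac-32 (2.97 ± 0.18), F48E3.2 (2.91 ± 0.10), T22F3.11 (2.81 ± 0.34), C06E4.3 (2.80 ± 0.17) and clec-258 (2.71 ± 0.14). Genes with smaller rises and very small p-values were argk-1 (2.42 ± 0.08), the lipase gene lipl-1 (2.3 ± 0.07), the galectin gene lec-2 (1.67 ± 0.06) and cth-1 (1.64 ± 0.05). Large falls were found in idpc-2 (-2.42 ± 0.31), srlf-34 (-2.31 ± 0.19), the ammonium transporter gene amt-1 (-2.11 ± 0.20), ora-1 (-2.1 ± 0.13), the chemoreceptor family gene str-144 (-1.98 ± 0.22) and pud-3 (-1.93 ± 0.26). Relative log expression factors gave 1446 higher and 2776 lower genes, library totals 2676 and 782, and DESeq2 1190 and 2791. The balance of rises and falls thus depends on the scaling, and without M04C9.5 replicate 2 the count was 2142.

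All 6 yolk protein genes fell (6 adjusted over the list alone), among them vit-3 (-1.62 ± 0.11), vit-4 (-1.51 ± 0.10), vit-5 (-1.11 ± 0.11) and vit-6 (-1.04 ± 0.12). Their share of counts was 2.18 ± 0.235% against 3.95 ± 0.14% (camera adjusted p = 9.11e-19, and adjusted p = 0.115 with an estimated correlation). Of 19 epidermal antimicrobial peptide genes 14 fell and 0 rose (15 fell adjusted over the list alone), with a median of -0.95 (camera adjusted p = 3.54e-24, and adjusted p = 0.0448 with an estimated correlation). cnc-4 (-1.84 ± 0.10), nlp-34 (-1.55 ± 0.11), nlp-29 (-1.53 ± 0.11) and nlp-31 (-1.23 ± 0.09) are members. Detoxification targets of the factor SKN-1 fell in 9 of 18 cases and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 2.06e-06, and adjusted p = 0.0498 with an estimated correlation). They include nit-1 (-1.32 ± 0.10), gst-4 (-1.03 ± 0.09) and gst-5 (-0.66 ± 0.07). In the tricarboxylic acid and glyoxylate cycle 14 of 22 genes fell and 1 rose (14 and 1 adjusted over the list alone), with icl-1 at -0.64 ± 0.05, mdh-2 at -0.32 ± 0.06 and fum-1 at -0.27 ± 0.06 (camera adjusted p = 4.52e-05, and adjusted p = 0.609 with an estimated correlation).

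Genes of ciliated neurons, a list without dyf-5, rose in 11 of 48 cases and fell in 2 (14 and 2 adjusted over the list alone). dyf-7 (1.8 ± 0.17), klp-11 (0.84 ± 0.11) and osm-1 (0.46 ± 0.09) are among the rises (median 0.33; camera adjusted p = 0.0123, and adjusted p = 0.490 with an estimated correlation). Among cuticle collagens named by phenotype, 7 of 20 rose and 0 fell (7 adjusted over the list alone). Examples are dpy-14 (1.94 ± 0.16), dpy-17 (1.27 ± 0.10) and sqt-3 (1.11 ± 0.13; camera adjusted p = 7.17e-04, and adjusted p = 0.784 with an estimated correlation). Of the 110 col genes, 27 fell and 10 rose (27 and 13 adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.825 with an estimated correlation). The gene col-122 had -0.67 ± 0.05 and col-99 1.82 ± 0.13. Fatty acid oxidation genes fell in 15 of 43 cases and rose in 4 (17 and 4 adjusted over the list alone), acdh-1 by -1.24 ± 0.10 (camera adjusted p = 0.00285, and adjusted p = 0.268 with an estimated correlation).

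**Figure D2:**
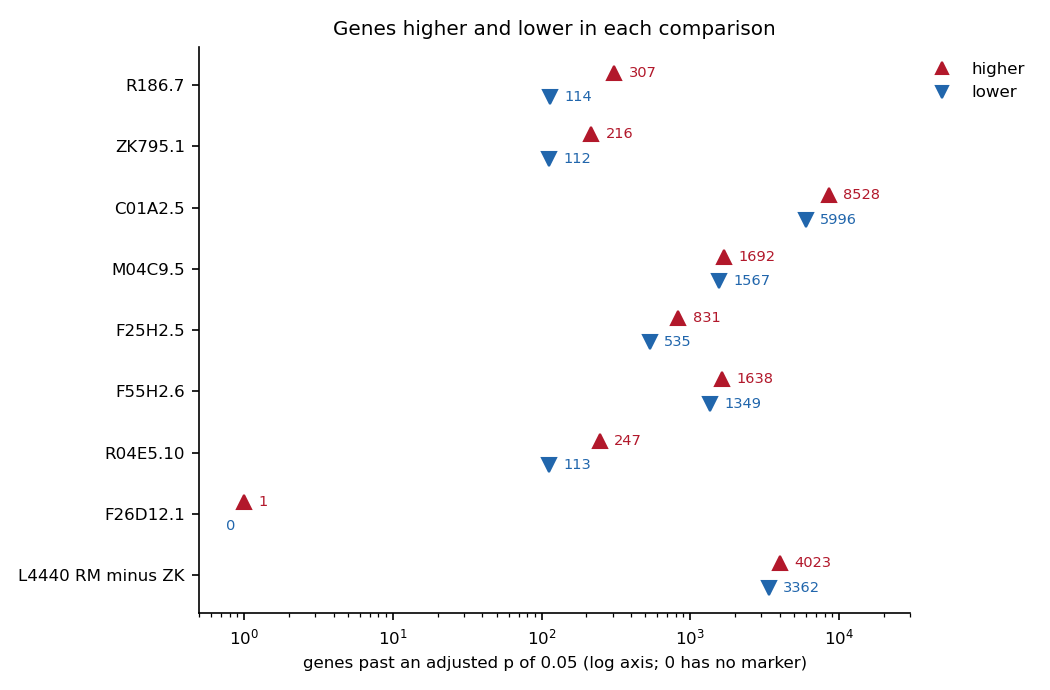
Number of genes higher and lower at an adjusted p of 0.05 in each RNAi treatment against its L4440 group and in L4440_RM against L4440_ZK, on a log axis. The counts run from 1 gene in the libraries labelled F26D12.1 to 14524 after C01A2.5 RNAi.

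F25H2.5 is ndk-1, a nucleoside diphosphate kinase gene (WBGene00009119, protein coding), at chromosome I 10553116 to 10553913 of WBcel235. It fell from 1298 ± 51.7 CPM in L4440_RM to 58.8 ± 12.07, a log2 fold change of -4.46 ± 0.14 (adjusted p = 3.20e-11). Its levels were 69.9, 46 and 60.6 CPM in the RNAi libraries and 1319, 1239 and 1335 in the controls. The neighbouring genes F25H2.6, 453 bp away (-1.13 ± 0.06), and F25H2.7, 4410 bp away (-1.03 ± 0.09), also fell, while F25H2.4 at 69 bp had -0.07 ± 0.08 (adjusted p = 0.621). The linker histone family gene hil-8 (-2.13 ± 0.25) and fog-3 (-1.53 ± 0.18), which directs germ cells to the sperm fate, fell. In the endoplasmic reticulum unfolded protein response 5 of 21 genes rose, and of 47 autophagy and lysosome genes 8 rose and 1 fell (adjusted p = 0.527 and 0.251 for the lists with an estimated correlation).

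Of 15795 genes tested, 1366 changed after F25H2.5 RNAi, 831 upward and 535 downward, with 42 rises and 90 falls over 2-fold. The methyltransferase gene icmt-1 (2.24 ± 0.37), C06E4.3 (1.5 ± 0.28), F20G2.1 (1.35 ± 0.26), npr-41 (1.18 ± 0.14) and the homeobox gene unc-39 (1.16 ± 0.24) were among the largest rises. F33H2.3 (0.87 ± 0.07) and C49F5.6 (0.74 ± 0.06) had among the smallest p-values. Further large falls were in nspd-10 (-1.59 ± 0.35), the cadherin gene cdh-7 (-1.54 ± 0.33), fipr-1 (-1.43 ± 0.37) and C07G1.7 (-1.31 ± 0.18). The count fell to 632, 431 or 833 without F25H2.5 replicate 1, 2 or 3 and to 641, 842 or 754 without L4440_RM replicate 1, 2 or 3.

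In the endoplasmic reticulum unfolded protein response, 5 of 21 genes rose and 0 fell (10 adjusted over the list alone). The kinase gene pek-1 (0.45 ± 0.09), cup-2 (0.29 ± 0.06) and dnj-7 (0.26 ± 0.06) are members (camera adjusted p = 2.58e-04, and adjusted p = 0.527 with an estimated correlation). The mitochondrial unfolded protein response list went the other way, with 5 of 15 genes falling and 0 rising (6 adjusted over the list alone). These include hsp-6 (-0.66 ± 0.11), spg-7 (-0.58 ± 0.10) and atfs-1 (-0.29 ± 0.07; camera adjusted p = 7.64e-04, and adjusted p = 0.534 with an estimated correlation). Autophagy and lysosome genes rose in 8 of 47 cases and fell in 1 (8 and 1 adjusted over the list alone). Among the rises were atg-16.2 (0.38 ± 0.07), epg-7 (0.35 ± 0.07) and lgg-1 (0.31 ± 0.06; camera adjusted p = 0.0128, and adjusted p = 0.251 with an estimated correlation). Of 43 intestinal immune effector genes 5 rose and 0 fell (7 adjusted over the list alone), with lys-7 at 0.77 ± 0.15 and spp-2 at 0.70 ± 0.15 (camera adjusted p = 2.12e-04, and adjusted p = 0.534 with an estimated correlation). Among 43 small RNA pathway genes 7 fell and 2 rose (9 and 5 adjusted over the list alone; camera adjusted p = 0.0583). Falls were seen in the Argonaute gene ppw-2 (-0.61 ± 0.11), the double-stranded RNA channel gene sid-1 (-0.48 ± 0.08) and rde-11 (-0.40 ± 0.07). Mitochondrial ribosomal protein genes fell in 10 of 65 cases and rose in 1 (16 and 2 adjusted over the list alone), as mrpl-22 (-0.57 ± 0.07) and mrps-30 (-0.36 ± 0.05) did (camera adjusted p = 0.00336, and adjusted p = 0.845 with an estimated correlation).

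Collagen, sperm and muscle lists lay low after F25H2.5 RNAi with few members past the test. The median of 122 collagen genes was -0.99 with 1 fall and 0 rises (0 and 0 adjusted over the list alone; camera adjusted p = 6.49e-07, and adjusted p = 0.795 with an estimated correlation). That of 26 major sperm protein genes was -0.95 with 2 falls, msp-57 (-1.31 ± 0.27) among them (3 adjusted over the list alone; camera adjusted p = 8.88e-08, and adjusted p = 0.655 with an estimated correlation). In muscle 3 of 38 genes fell (6 adjusted over the list alone), including unc-68 (-0.56 ± 0.11) and myo-1 (-0.74 ± 0.19; camera adjusted p = 2.27e-08, and adjusted p = 0.695 with an estimated correlation). The cuticle collagens named by phenotype had a mean log2 level of 0.80 in L4440_RM replicate 3 against 2.74 and 3.26 in the other L4440_RM libraries, of 0.61 in F26D12.1 replicate 3 against 3.12 and 2.64, of 0.81 in F25H2.5 replicate 3 against 1.38 and 1.43, and of 0.93 in F55H2.6 replicate 3 against 1.81 and 2.2. In the libraries labelled R04E5.10 replicate 3 was not low, at 1.6 against 1.41 and 1.52. With replicates 1 and 2 alone in every RM group, an alternative chosen after the data were seen, 29 collagen genes fell and 0 rose, and F25H2.5 RNAi changed 748 genes, 319 upward and 429 downward.

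F55H2.6 is clu-1, the clustered mitochondria homolog (WBGene00000550, protein coding), at chromosome III 9516631 to 9521460 of WBcel235. Its transcript fell to 127.5 ± 7.83 from 268.9 ± 32.9 CPM (-1.08 ± 0.10, adjusted p = 6.00e-06), with 123.5, 136.5 and 122.5 CPM in the RNAi libraries and 277.6, 296.6 and 232.6 in the controls. Of its neighbours, F55H2.7 at 383 bp (-0.36 ± 0.08) and prp-40 at 615 bp (-0.18 ± 0.05) fell. F55H2.5 at 3256 bp rose (0.46 ± 0.08), and mrps-23 and trpp-3 did not pass. Falls were found in 30 of 44 nuclear genes of oxidative phosphorylation, 32 of 65 mitochondrial ribosomal protein genes, 13 of 22 genes of the tricarboxylic acid and glyoxylate cycle and 10 of 12 genes of the mitochondrial genome. Each list passed with the preset correlation and not with an estimated one (adjusted p = 0.400, 0.534, 0.400 and 0.376 with an estimated correlation). The glycolytic genes aldo-1, from 56.2 ± 7.25 to 403.0 ± 24.9 CPM (2.84 ± 0.12), and ldh-1 (1.39 ± 0.07) rose.

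After F55H2.6 RNAi 2987 of 15795 genes changed, 1638 upward and 1349 downward, and 482 of the rises but 15 of the falls were over 2-fold. R07C12.3 (4.93 ± 0.33), nimk-1 (4.11 ± 0.35), ZK177.9 (3.69 ± 0.18), osg-1 (3.66 ± 0.17), hrg-9 (3.37 ± 0.17) and the ligand-gated channel gene lgc-30 (3.23 ± 0.19) were among the largest rises. The neuropeptide receptor gene pdfr-1 (2.89 ± 0.10), the folate transporter gene folt-1 (2.78 ± 0.11) and C46C2.2 (2.05 ± 0.10) had among the smallest p-values. Besides clu-1, the largest falls included the insulin-like gene ins-19 (-1.71 ± 0.44), cyp-35A3 (-1.41 ± 0.32), hsp-60 (-1.36 ± 0.14), the lipoamide dehydrogenase gene dld-1 (-1.14 ± 0.10) and the mitochondrial protease gene spg-7 (-1.04 ± 0.10). Relative log expression factors gave 1337 higher and 1869 lower genes, library totals 2326 and 545, and DESeq2 1224 and 2277. Without F55H2.6 replicate 3 the count was 1365, without L4440_RM replicate 1 it was 1611, and without L4440_RM replicate 3 it was 1726. F55H2.6 replicate 1 had 3.58% of its counts in ribosomal RNA genes against 0.472% and 0.372% in the other libraries of its group, and the chi-square of its counts over genes per degree of freedom against these was 85.98 and 85.23, where the highest value of any other replicate pair was 39.95; without it 2985 genes changed.

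Of 44 nuclear genes of oxidative phosphorylation 30 fell and 0 rose (33 and 1 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 1.93e-24, and adjusted p = 0.400 with an estimated correlation). Examples are cox-4 (-0.94 ± 0.10), nduf-2.2 (-0.85 ± 0.09) and sdha-2 (-0.84 ± 0.08). Of the 12 protein-coding genes of the mitochondrial genome 10 fell (11 adjusted over the list alone). Examples are mt:COX3 (-0.81 ± 0.12), mt:ND1 (-0.74 ± 0.09) and mt:ND5 (-0.73 ± 0.10; camera adjusted p = 1.39e-13, and adjusted p = 0.376 with an estimated correlation). Mitochondrial ribosomal protein genes fell in 32 of 65 cases and 0 rose (36 fell adjusted over the list alone), such as mrpl-22 (-0.91 ± 0.07; camera adjusted p = 3.05e-14, and adjusted p = 0.534 with an estimated correlation). In the tricarboxylic acid and glyoxylate cycle 13 of 22 genes fell and 0 rose (14 fell adjusted over the list alone), with idhg-1 at -0.73 ± 0.08 and mdh-2 at -0.66 ± 0.10 (camera adjusted p = 2.38e-13, and adjusted p = 0.400 with an estimated correlation). The pyruvate dehydrogenase genes pdhb-1 (-0.82 ± 0.09) and pdha-1 (-0.75 ± 0.06) fell while aldo-1 and ldh-1 rose. The 25 glycolysis and gluconeogenesis genes as a list, with 4 rises and 8 falls (4 and 9 adjusted over the list alone), did not pass (camera adjusted p = 0.406). The mitochondrial unfolded protein response list had 3 falls, hsp-60, spg-7 and hsp-6 (-0.56 ± 0.11), and 1 rise among 15 genes (4 and 1 adjusted over the list alone). Its median of -0.06 turned to 0.04 with library totals (camera adjusted p = 0.0121, and adjusted p = 0.622 with an estimated correlation).

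Oocyte, eggshell and early embryo genes fell in 23 of 32 cases after F55H2.6 RNAi and 0 rose (25 and 1 adjusted over the list alone). They include cey-2 (-0.51 ± 0.07), oma-2 (-0.47 ± 0.08) and the chitin synthase gene chs-1 (-0.42 ± 0.07; camera adjusted p = 6.80e-14, and adjusted p = 0.534 with an estimated correlation). Germline proliferation and meiosis genes fell in 20 of 42 cases (27 fell and 1 rose adjusted over the list alone), such as the germ granule gene pgl-1 (-0.43 ± 0.06; camera adjusted p = 5.57e-11, and adjusted p = 0.534 with an estimated correlation). Proteasome genes fell in 16 of 33 cases (21 adjusted over the list alone), such as rpn-11 (-0.45 ± 0.06; camera adjusted p = 7.76e-10, and adjusted p = 0.534 with an estimated correlation). Intestinal immune effector genes rose in 11 of 43 cases and 0 fell (13 and 1 adjusted over the list alone), with spp-18 at 1.1 ± 0.15 and spp-2 at 0.92 ± 0.15 (camera adjusted p = 8.87e-04, and adjusted p = 0.546 with an estimated correlation). Of 25 pals genes, a family that rises on intracellular infection, 6 rose and 0 fell (8 adjusted over the list alone), pals-16 by 1.05 ± 0.14 (camera adjusted p = 0.00663, and adjusted p = 0.376 with an estimated correlation). Collagen genes had a median of -0.75 although 5 of 122 rose and 1 fell (4 and 0 adjusted over the list alone; camera adjusted p = 7.17e-04, and adjusted p = 0.878 with an estimated correlation). With replicates 1 and 2 alone in every RM group, which leaves out the libraries lowest in collagen transcripts in both F55H2.6 and L4440_RM, 20 fell and 2 rose, and 784 genes changed in all.

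**Figure D3:**
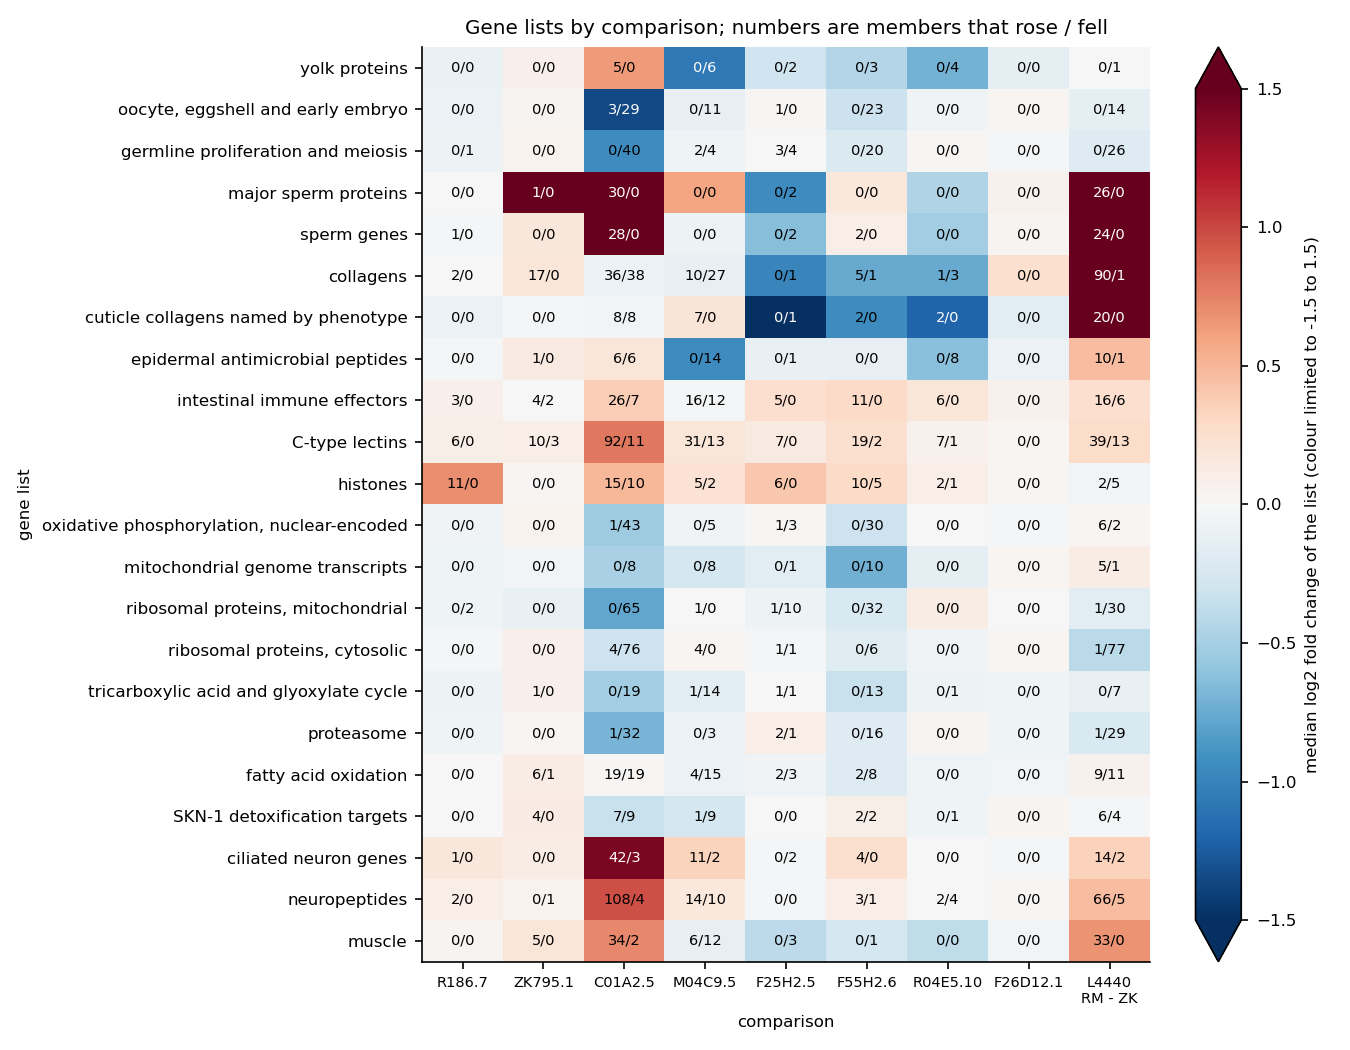
Median log2 fold change of 22 gene lists (vertical) in the 8 RNAi comparisons and in L4440_RM against L4440_ZK (horizontal), with colours limited to -1.5 and 1.5 and, in each cell, the number of members that rose and fell. Yolk protein genes are low in the libraries labelled M04C9.5 (-1.07) and R04E5.10 (-0.71), oxidative phosphorylation genes after F55H2.6 RNAi (-0.32), and sperm genes are high after C01A2.5 RNAi (8.00, beyond the colour range); each keeps its sign with every scaling tried.

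R04E5.10 is ifd-1, an intermediate filament gene of the intestine (WBGene00002057, protein coding), at chromosome X 8820703 to 8824448 of WBcel235. In the libraries labelled R04E5.10 its transcript was higher, not lower, at 21.8 ± 3.91 against 5.40 ± 2.07 CPM in L4440_RM, a log2 fold change of 2.01 ± 0.25 (adjusted p = 9.98e-04). The treated libraries held 22.9, 17.4 and 25.0 CPM and the controls 5.48, 7.43 and 3.28. As with dyf-5, the counts do not show whether the label or the clone is right. In the libraries labelled R04E5.10, 4 of 6 yolk protein genes and 8 of 20 epidermal antimicrobial peptide genes fell, for example vit-4 (-1.14 ± 0.13) and cnc-4 (-1.25 ± 0.21; adjusted p = 0.0498 for both lists with an estimated correlation). The linker histone gene his-24 rose (1.17 ± 0.13), from 14.5 ± 3.39 to 32.5 ± 1.57 CPM.

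In these libraries 360 of 15795 genes changed, 247 upward and 113 downward, with 128 rises and 27 falls over 2-fold. F20G2.1 (3.08 ± 0.26), C06E4.3 (3.03 ± 0.28), T22F3.11 (2.96 ± 0.53), fmo-2 (2.56 ± 0.38), the insulin-like gene ins-2 (2.29 ± 0.26), unc-39 (2.15 ± 0.23), math-38 (2.15 ± 0.30) and ugt-32 (2.08 ± 0.44) rose most. Small p-values were found for cutl-16 (1.45 ± 0.16), Y46G5A.7 (1.22 ± 0.13) and the RNA-binding protein gene sup-26 (0.69 ± 0.08). The largest falls included F18E3.12 (-1.70 ± 0.33), str-144 (-1.35 ± 0.26), fipr-26 (-1.33 ± 0.19), vit-3 (-1.31 ± 0.23), srlf-34 (-1.3 ± 0.20), cnc-6 (-1.27 ± 0.30) and cnc-4. DESeq2 called 609 genes, 350 higher and 259 lower. The count fell to 200 or 133 without R04E5.10 replicate 1 or 3 and to 161 or 173 without L4440_RM replicate 1 or 3.

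Yolk protein genes fell in 4 of 6 cases and 0 rose in the libraries labelled R04E5.10 (6 fell adjusted over the list alone), with vit-5 at -0.68 ± 0.12 and vit-6 at -0.57 ± 0.10. The list had a median of -0.71 and 2.67 ± 0.09% of counts against 3.90 ± 0.42% (camera adjusted p = 6.40e-20, and adjusted p = 0.0498 with an estimated correlation). Of 20 epidermal antimicrobial peptide genes 8 fell and 0 rose (13 fell adjusted over the list alone). Members are nlp-29 (-0.99 ± 0.15) and nlp-27 (-0.61 ± 0.11; camera adjusted p = 1.22e-16, and adjusted p = 0.0498 with an estimated correlation). Intestinal immune effector genes rose in 6 of 43 cases and 0 fell (16 and 3 adjusted over the list alone). Examples are ilys-3 (1.38 ± 0.31), spp-2 (1.00 ± 0.15) and spp-8 (0.73 ± 0.10; camera adjusted p = 2.33e-06, and adjusted p = 0.534 with an estimated correlation). The protease gene cpr-1 (1.6 ± 0.29), lipl-1 (1.41 ± 0.24) and cyp-37B1 (1.1 ± 0.18) rose, and ugt-53 fell (-1.15 ± 0.18). Muscle genes had a median of -0.38 with 0 of 38 past the test over all genes and 14 falls adjusted over the list alone (camera adjusted p = 2.03e-13, and adjusted p = 0.534 with an estimated correlation). Collagens had a median of -0.75, with 3 falls, col-96 (-0.98 ± 0.16) among them, and 1 rise, col-165 (1.89 ± 0.40), in 122 genes (7 and 3 adjusted over the list alone; camera adjusted p = 6.48e-08, and adjusted p = 0.795 with an estimated correlation). With replicates 1 and 2 alone in every RM group, which leaves out the low L4440_RM replicate 3 and a R04E5.10 replicate 3 that was not low, 17 collagen genes fell and 0 rose, and the libraries labelled R04E5.10 had 76 higher and 179 lower genes.

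F26D12.1 is fkh-7, a forkhead transcription factor gene (WBGene00001439, protein coding), at chromosome IV 5584684 to 5610378 of WBcel235. In the libraries labelled F26D12.1 it was not lowered, at 26.6 ± 8.12 against 22.6 ± 0.96 CPM (0.23 ± 0.15, adjusted p = 1.00), with 18.1, 27.5 and 34.2 CPM in the treated libraries and 21.5, 23.4 and 23.0 in L4440_RM. A wrong label or clone is not excluded here either. Of 15795 genes 1 changed, msa-1, which rose from 70.7 ± 6.64 to 117.0 ± 4.66 CPM (0.73 ± 0.09, adjusted p = 0.00501). With edgeR 360 genes had an unadjusted p under 0.05, and DESeq2 called 5 genes at an adjusted p of 0.05. The call of msa-1 was lost, leaving 0 genes, without L4440_RM replicate 1 or 2 and in a fit of the 6 libraries compared, and 2 genes were called without F26D12.1 replicate 2 and with replicates 1 and 2 alone in every RM group. No member of any gene list passed over all genes. Genes raised by DAF-16 had 4 rises adjusted over the list alone (median 0.03; camera adjusted p = 6.44e-04, and adjusted p = 0.539 with an estimated correlation), and the 33 proteasome genes had a median of -0.06 with 0 changes adjusted over the list alone (camera adjusted p = 7.61e-06, and adjusted p = 0.733 with an estimated correlation).

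The L4440 libraries allow the same empty vector to be compared between the prefixes. In L4440_RM 90 of 124 collagen, 26 of 30 major sperm protein and 33 of 38 muscle genes were higher than in L4440_ZK, and 77 of 83 cytosolic ribosomal protein and 26 of 42 germline genes lower. None of these 5 lists passed with an estimated correlation (adjusted p = 0.294 to 0.571). Of 16867 genes tested in all 30 libraries, 7385 differed, 4023 higher and 3362 lower in L4440_RM, and of the 2105 genes that differed by more than 2-fold 1870 were higher. The side with more genes turned with relative log expression factors (3562 higher and 3942 lower), with DESeq2 (3223 and 3938) and without replicate 2 of L4440_RM (3023 and 3108) or of L4440_ZK (3035 and 3107). The largest differences were in C07G1.7 (6.11 ± 0.30), col-176 (4.68 ± 0.81), the cuticle collagen genes rol-6 (4.13 ± 0.82) and sqt-1 (3.83 ± 0.79) and msp-45 (4.00 ± 0.71) on the higher side. On the lower side they were in Y37H2A.13 (-2.49 ± 0.18), dyf-3 (-2.22 ± 0.38), ins-19 (-2.15 ± 0.35), tbx-38 (-2.09 ± 0.33) and lys-10 (-2.05 ± 0.26).

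Of 124 collagen genes 90 were higher and 1 lower in L4440_RM (98 and 1 adjusted over the list alone), with a median of 1.67 (camera adjusted p = 3.78e-09, and adjusted p = 0.571 with an estimated correlation). All 20 cuticle collagens named by phenotype were higher (20 adjusted over the list alone), such as dpy-9 (2.48 ± 0.35) and dpy-10 (0.80 ± 0.14; camera adjusted p = 4.36e-07, and adjusted p = 0.470 with an estimated correlation). Their mean log2 level was 2.74, 3.26 and 0.80 in the L4440_RM libraries and -0.19, 0.68 and -1.07 in L4440_ZK. Major sperm protein genes were higher in 26 of 30 cases (28 adjusted over the list alone), msp-142 by 3.37 ± 0.44 (camera adjusted p = 7.73e-11, and adjusted p = 0.322 with an estimated correlation). Other sperm genes were higher in 24 of 28 cases (25 adjusted over the list alone), with gsp-3 at 2.85 ± 0.42 and fer-1 at 1.11 ± 0.15 (camera adjusted p = 7.73e-11, and adjusted p = 0.294 with an estimated correlation). Muscle genes were higher in 33 of 38 cases (33 adjusted over the list alone), including myo-2 (0.79 ± 0.13; camera adjusted p = 4.06e-10, and adjusted p = 0.418 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 77 of 83 cases and higher in 1 (78 and 1 adjusted over the list alone), rps-9 by -0.73 ± 0.08 (camera adjusted p = 2.28e-32, and adjusted p = 0.294 with an estimated correlation). Germline proliferation and meiosis genes were lower in 26 of 42 cases (26 adjusted over the list alone), for example pgl-1 (-0.42 ± 0.06; camera adjusted p = 1.24e-08, and adjusted p = 0.322 with an estimated correlation).

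**Figure D4:**
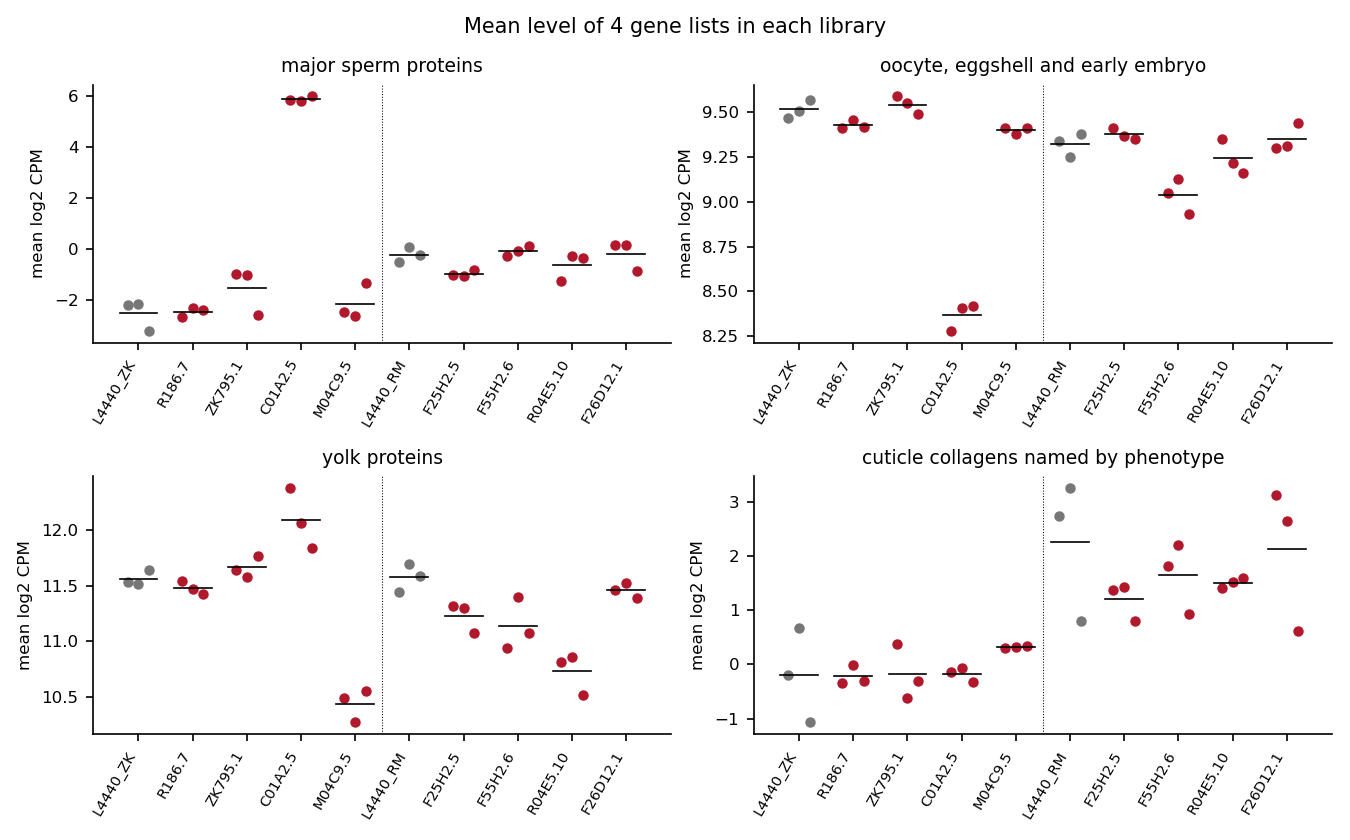
Mean log2 CPM of 4 gene lists (major sperm proteins; oocyte, eggshell and early embryo; yolk proteins; cuticle collagens named by phenotype) in each of the 30 libraries, arranged by group. Major sperm proteins reached 5.88, 5.84 and 6.01 in the C01A2.5 libraries against -2.19, -2.15 and -3.21 in L4440_ZK, and the collagens lay at 2.74, 3.26 and 0.80 in L4440_RM.

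Across the 8 comparisons 118 of 368 list tests passed with camera's preset correlation, 41 upward and 77 downward. With an estimated correlation 7 passed: histones after R186.7 RNAi, fatty acid oxidation after ZK795.1 RNAi, sperm genes after C01A2.5 RNAi, antimicrobial peptides and SKN-1 targets in the libraries labelled M04C9.5, and yolk proteins and antimicrobial peptides in the libraries labelled R04E5.10.

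The libraries labelled M04C9.5 and R04E5.10, in which the targeted gene was higher and not lower, share no library and no control, yet Pearson's r of their fold changes was the highest among the pairs of comparisons from different prefixes, while Spearman's rho was higher for C01A2.5 and F55H2.6 RNAi (0.57). Across 11104 genes with a control level of at least 1 CPM, Pearson's r was 0.70 and Spearman's rho 0.53 (genes are not independent replicates), against a median r of 0.03 over the 16 pairs of comparisons from different prefixes, whose range was -0.22 to 0.70. Both raised 229 genes where 26.1 would be shared by independent lists of their sizes. In all, 93.1% of the rises and 92.0% of the falls in the libraries labelled R04E5.10 were also found in those labelled M04C9.5, and 0 genes moved in opposite directions. A test of the difference between the effects passed for 20 genes. F20G2.1, C06E4.3, fmo-2 and T22F3.11 are among the shared rises and vit-3, vit-4, cnc-4, nlp-29, srlf-34 and str-144 among the shared falls.

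**Figure D5:**
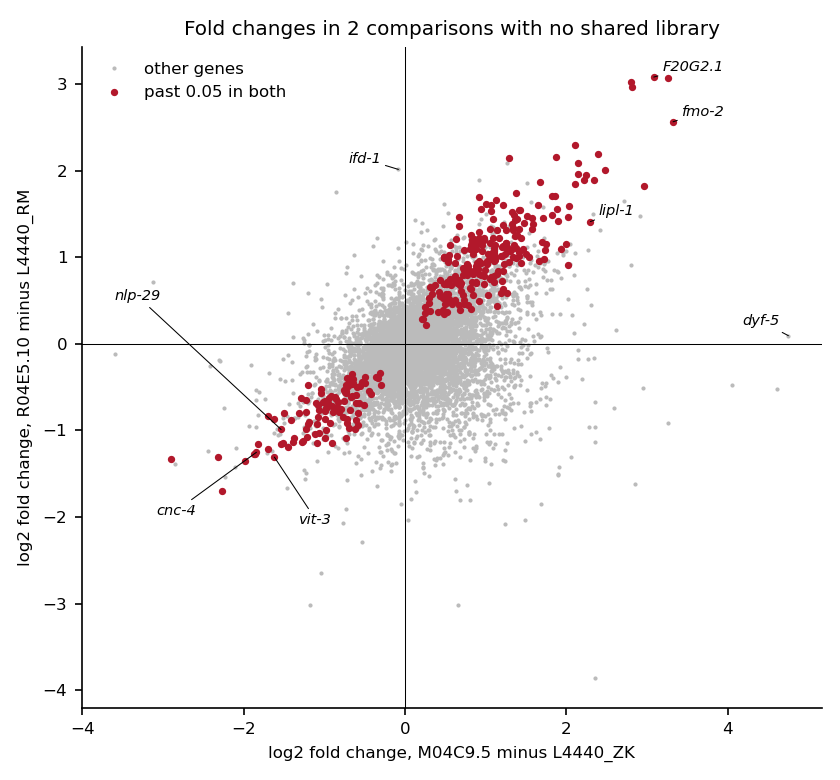
Log2 fold changes of single genes in the libraries labelled M04C9.5 against L4440_ZK (horizontal) and in those labelled R04E5.10 against L4440_RM (vertical), with genes past an adjusted p of 0.05 in both in red. The red genes lie at the upper right, 229 of them, and at the lower left, and r across genes is 0.70.

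C01A2.5 and F55H2.6 RNAi, also from different prefixes, both raised 1172 genes (786.0 for independent lists) and both lowered 1282 (519.2), with r = 0.45 across genes. After C01A2.5 and F55H2.6 RNAi, 29 and 23 of 32 oocyte genes, 40 and 20 of 42 germline genes, 65 and 32 of 65 mitochondrial ribosomal protein genes and 32 and 16 of 33 proteasome genes fell (adjusted p = 0.534 with an estimated correlation for each of these lists in both). F55H2.6 RNAi shared 592 rises with the libraries labelled M04C9.5 (169.7 for independent lists; r = 0.40) and 118 with R186.7 RNAi (31.4; r = 0.38). Negative correlations were found for ZK795.1 RNAi, with r = -0.22 against the libraries labelled R04E5.10 and r = -0.17 against F25H2.5 RNAi.

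Comparisons within a prefix share their 3 controls, and simulated unchanged groups against those controls gave a median r of 0.51. The observed median over 12 such pairs was 0.26. Real changes widen the fold changes of a comparison and so shift r, and setting these medians side by side does not measure likeness. For each pair with the libraries labelled F26D12.1 the covariance was below the simulated one, for example 0.0033 against 0.0183 with those labelled R04E5.10. Covariances were above the simulated ones in some other pairs. They were 0.0264 against 0.0060 for R186.7 RNAi and the libraries labelled M04C9.5, which shared 160 rises (31.5 for independent lists). They were 0.0106 against 0.0060 for R186.7 and ZK795.1 RNAi with 39 (4.0), and 0.0654 against 0.0183 for F25H2.5 RNAi and the libraries labelled R04E5.10 with 84 (13.0). The 3 controls of a prefix cannot be split into groups of 2, so part of these excesses may come from the shared controls. The simulations also drew each library independently, while RM libraries with the same replicate number had correlations of up to 0.552. An excess over the simulated covariance thus does not by itself measure likeness. argk-1, cth-1, clec-258 and F48E3.2 rose in all 4 ZK comparisons. C06E4.3 and lipl-1 rose in 7 of the 8 comparisons, and clec-218, gst-29, his-32, jmjd-3.2, C14C6.5 and C40A11.4 in 6. The exception for C06E4.3 (0.20) and lipl-1 (0.35) was the comparison of the libraries labelled F26D12.1, and C14C6.5 fell after ZK795.1 RNAi (-0.44).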

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

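Some genes passed the test in a pair of comparisons with opposite signs and also passed the test of the difference between them. The test of the difference removed few genes and adds little support. It kept 955 of 958 for C01A2.5 RNAi and the libraries labelled M04C9.5. The counts were not set against those of independent lists. A count by itself thus does not show that 2 effects oppose each other. With 14524 of 16495 genes changed after C01A2.5 RNAi, many opposite signs arise in its pairs without any link. Signs after C01A2.5 RNAi also depend on the scaling, with a median of 0.42 over all genes. R186.7 and C01A2.5 RNAi, for example, shared 178 rises and 102 falls. R186.7 and C01A2.5 RNAi moved 100 genes in opposite directions, 92 of them higher after R186.7 RNAi and 8 higher after C01A2.5 RNAi. ZK795.1 and C01A2.5 RNAi did so for 122 genes, 44 of them higher after ZK795.1 RNAi; the lysozyme gene lys-7 fell after ZK795.1 RNAi (-0.73 ± 0.06) and rose after C01A2.5 RNAi (1.13 ± 0.06), as did ins-7 (-0.93 ± 0.09 and 2.48 ± 0.08). Between ZK795.1 RNAi and the libraries labelled M04C9.5, in which dyf-5 was not lowered, 142 genes went opposite ways, 108 of them higher after ZK795.1 RNAi. Among these are icl-1 (0.34 ± 0.05 and -0.64 ± 0.05), ftn-1 (0.64 ± 0.09 and -0.94 ± 0.09), gst-4 (0.38 ± 0.08 and -1.03 ± 0.09) and col-122 (0.39 ± 0.05 and -0.67 ± 0.05).

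C01A2.5 RNAi and the libraries labelled M04C9.5 differed in sign for 955 genes, 668 of them higher after C01A2.5 RNAi, with the yolk protein gene vit-6 at 0.56 ± 0.11 and -1.04 ± 0.12. For C01A2.5 and F25H2.5 RNAi the count was 729, with 563 of them higher after F25H2.5 RNAi. C01A2.5 and F55H2.6 RNAi had 233 such genes, 21 of them higher after C01A2.5 RNAi. C01A2.5 RNAi and the libraries labelled R04E5.10, in which ifd-1 was not lowered, had 116, of which 65 were higher after C01A2.5 RNAi. The libraries labelled M04C9.5 and F25H2.5 RNAi had 113, of which 23 were higher in the former. They also shared 136 rises (88.0 for independent lists) and 32 falls (53.6). F25H2.5 and F55H2.6 RNAi had 106, of which 65 were higher after F25H2.5 RNAi. This pair also shared 183 rises (86.2 for independent lists) and 145 falls (45.7).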

How the results depend on the processing

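The cause of the shifts in the counts of changed genes was not tested. DESeq2 called 648 genes after R186.7 RNAi, 593 after ZK795.1 RNAi, 609 in the libraries labelled R04E5.10 and 5 in those labelled F26D12.1, and without the filter on low counts the last became 4, or 3 with relative log expression factors. A fit of all 30 libraries, with a spread between that of the prefixes, gave 161 for R186.7, 44 for ZK795.1, 1822 for M04C9.5, 2738 for F25H2.5, 939 for R04E5.10 and 4 for F26D12.1. Only the 6 libraries compared gave 2263 for F25H2.5, 1458 for F55H2.6, 153 for R04E5.10 and 0 for F26D12.1. All 6 L4440 libraries as 1 control gave 71 for ZK795.1, 2309 for F25H2.5, 7374 for F55H2.6, 952 for R04E5.10 and 16 for F26D12.1. With these 6 as 1 control, act-4 and tnt-2 after ZK795.1 RNAi turned to -0.12 and C14C6.5 after R186.7 RNAi to -0.00, without passing; the L4440 groups differ in 7385 genes. Replicates 1 and 2 alone in every RM group, chosen after the data were seen, gave 748 for F25H2.5, 784 for F55H2.6 and 2 for F26D12.1.

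Leaving out 1 library gave 245 (without L4440_ZK replicate 3) to 437 genes (without L4440_ZK replicate 1) for R186.7, with 266 and 254 without R186.7 replicate 1 and 2 and 268 without L4440_ZK replicate 2. For ZK795.1 the range was 190 (without ZK795.1 replicate 1) to 1304 (without ZK795.1 replicate 3), with 209 without L4440_ZK replicate 2. It was 14237 to 14511 for C01A2.5 and 2142 (without M04C9.5 replicate 2) to 3107 (without L4440_ZK replicate 3) for M04C9.5. For F25H2.5 the counts were 632, 431 and 833 without its replicates 1, 2 and 3 and 641, 842 and 754 without those of L4440_RM. The range was 1365 (without F55H2.6 replicate 3) to 3239 (without F55H2.6 replicate 2) for F55H2.6, with 1611 and 1726 without L4440_RM replicate 1 and 3. It was 133 (without R04E5.10 replicate 3) to 378 (without L4440_RM replicate 2) for R04E5.10, with 200 without R04E5.10 replicate 1 and 161 and 173 without L4440_RM replicate 1 and 3. For F26D12.1 it was 0 (without L4440_RM replicate 1 or 2) to 2 (without F26D12.1 replicate 2), and for the L4440 groups 6131 to 6774.

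The replicate number, which is the order of the title numbers within a group, was tried as a block. It gave 348, 299, 14490, 2998, 1464, 3104, 375 and 1 genes for the 8 treatments in the order of the text. It also gave 7343 genes for the L4440 groups, 121 list tests and a correlation of 0.255. After group means were removed, libraries with the same replicate number had a mean correlation of -0.013 in the ZK and 0.086 in the RM libraries. In these prefixes 3 and 9 of 15 libraries were most like a library of their own replicate number, where 5 are expected by chance. Of the pairs with the same replicate number 0 of 30 had a correlation over 0.1 in the ZK libraries. In the RM libraries 14 of 30 did, with a range of -0.193 to 0.552. The replicate numbers were not taken to pair samples in either prefix, a choice that the RM values do not settle. RM pairs with different replicate numbers had a lower mean of -0.042, and replicate 3 was the lowest in collagen transcripts in 4 of 5 RM groups. The main RM fit leaves such a shared structure in the spread between libraries. Of the 118 list tests that passed with the preset correlation, 7 passed with an estimated one. With fry 116 of all 368 tests passed, and these were not all the same tests. The oocyte list after R186.7 RNAi, for example, had a camera adjusted p of 9.42e-07 and a fry adjusted p of 0.142. The median correlation between comparisons was 0.255 with common controls, 0.030 without and 0.506 in simulated unchanged groups. Of 331 named gene results past the threshold, 236 kept their call in every alternative.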

Other observations

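Targets also moved in treatments aimed at other genes. After C01A2.5 RNAi, where the median of all genes was 0.42, clu-1 (-1.09 ± 0.06), pnn-1 (-0.93 ± 0.09) and ndk-1 (-0.87 ± 0.06) fell and dyf-5 (2.05 ± 0.29), ifd-1 (0.78 ± 0.12) and ipmk-1 (0.58 ± 0.10) rose. After F25H2.5 RNAi clu-1 fell (-0.67 ± 0.10) and pnn-1 rose (0.39 ± 0.07), and after F55H2.6 RNAi ndk-1 fell (-0.40 ± 0.12, edgeR adjusted p = 0.0367). The mitochondrial factor gene atfs-1 fell after C01A2.5 RNAi (-0.98 ± 0.05), as did the small heat shock gene sip-1 (-1.45 ± 0.06), while the pals gene pals-24 rose (1.42 ± 0.07). In L4440_RM the metallothionein gene mtl-2 was higher (1.72 ± 0.15) and the octopamine synthesis gene tbh-1 lower (-1.05 ± 0.11) than in L4440_ZK. Among detoxification genes gst-29 rose in 6 of 8 treatments, by 0.92 ± 0.14 after ZK795.1 RNAi.

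Of the tests of explanations, those of males, of a larval moult as the source of collagens in the L4440 groups, of scaling and of library splits were written down before their values were seen, and those of the last larval moult, of the germline, of double-stranded RNA reads, of exchanged labels, of a moult as the source of sperm genes, of tissue amounts and of the prefixes only after the result was seen.

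Sperm genes rose after C01A2.5 RNAi, and males in the cultures could be a source. Of 10 genes of male somatic tissue 5 could be tested, and their median of 2.83 (2.19 to 3.08 leaving out 1 gene) lay just short of the value of 3 set for males, while neuronal lists rose too, so males cannot be told apart from other sources. Whole cultures at or before the last larval moult are unlikely, because yolk protein genes, made by adults, had a median of 0.63. Moulting genes had a median of 1.11, or 0.68 above that of all genes and short of the value of 1 set for larvae, so a share of larvae is neither shown nor excluded. The oocyte median of -1.36 met the value set, after the result was seen, for a germline that makes sperm in place of oocytes. Germline proliferation and meiosis genes had a median of -0.94, so the fall was not particular to oocyte genes. Fewer oocytes would lower the oocyte genes whatever the source, so their median cannot tell these sources apart.

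The targets dyf-5 and ifd-1 were higher in the libraries labelled with them. More cells of the kind that holds the gene is unlikely for dyf-5, because the other ciliated neuron genes had a median of 0.33. The other intermediate filament genes had a median of -0.16. That list is drawn by gene family and does not measure the amount of intestine, so for ifd-1 it cannot decide. Reads of the double-stranded RNA itself cannot be told apart from transcript, because counts per gene do not show where in the gene the reads lie. In other groups of the same prefix the highest values were 2.05 for dyf-5, after C01A2.5 RNAi, and 0.05 for ifd-1. Each target was thus higher under its own label by the margin set for such reads. None of the tested genes near it passed, with ppfr-1 at 0.12 ± 0.06 and rcs-1 at 0.10 ± 0.09. Such reads would give that pattern, and so would a rise of the transcript itself. An exchange of labels or clones with a treatment whose target fell is unlikely, because the lowest value of those 5 targets was -0.11 in these libraries. No sign of an exchange with each other or with F26D12.1 was seen either, with ifd-1 at -0.08 ± 0.13 in the libraries labelled M04C9.5 and -0.03 ± 0.26 in those labelled F26D12.1, and fkh-7 at 0.08 ± 0.07 and 0.18 ± 0.15 in those labelled M04C9.5 and R04E5.10, but a clone that does not lower its target, or one from elsewhere, would leave no such sign and stays open.

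Collagen and sperm genes were higher in L4440_RM than in L4440_ZK, and for the collagen genes animals at a larval moult among those collected fit a median difference of 0.90 in moulting genes. The clause on the third replicate was written with its low collagen level already known: moulting genes had mean log2 levels of 3.13, 3.56 and 2.44 in L4440_RM against 2.11, 2.27 and 1.92, but 2.92, 2.93 and 3.00 in F55H2.6, whose replicate 3 is also low in collagens. In the C01A2.5 libraries moulting genes lay at 3.28, 3.40 and 3.29, but the cuticle collagens named by phenotype at -0.14, -0.07 and -0.32. High moulting genes thus need not go with high collagens, and the fit does not show a moult. For the sperm genes a moult cannot be told apart from other sources, because they did not drop in L4440_RM replicate 3, at 0.94 against 0.64 and 0.95 (0.15 above the mean of these), and 1 library excludes nothing. Scaling between libraries is unlikely, because the collagen median was 1.64 with relative log expression factors. The labels do not say whether the prefixes mark batches. A difference between such batches cannot be told apart, as 0 libraries of either L4440 group carry the other prefix.

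The 6 libraries of each comparison can be split in 10 ways, too few for a share under 0.05. The real split called the most genes, 1 of 10, with 0 in the highest other split, for R186.7, C01A2.5, F25H2.5, F55H2.6 and the libraries labelled M04C9.5 and R04E5.10, and with 14 in the highest other split for the L4440 groups. For ZK795.1, 2 of 10 splits were as large, and the other one called 337 genes with ZK795.1 replicates 1 and 2 beside L4440_ZK replicate 3, which points to a structure of the samples. For the libraries labelled F26D12.1, 3 of 10 splits called as many genes as the real one, the highest 722, with F26D12.1 replicates 2 and 3 and L4440_RM replicate 3 against the rest, which also points to a structure of the samples.

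The deposited RPKM values would distort a comparison between libraries, since each value was scaled by a total that was 0.708 to 1.41 times that of its own library.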
